A study of Arabidopsis thaliana with 20 samples.

How the data were processed

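Cells of the Arabidopsis suspension line T87 were held at 22 °C or moved to 4 °C for 6, 12, 24 or 36 h, and cordycepin was then added to stop transcription. Total RNA was read on Affymetrix ATH1 arrays, with 20 arrays in 5 series of 4. The 22 °C series was sampled at 0, 0.5, 2 and 4 h of cordycepin and each cold series at 0, 4, 8 and 12 h. Every combination has 1 array, so no condition has replicates. The cold cells also stood in dimmer light, 40 against 80 µmol per square metre and second, and cold duration runs with time in culture. The growth protocol gives 12, 24 and 36 h of cold, and the sample titles and the design text also give 6 h, which was used here.

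The deposited values are probe set intensities that the authors summarised with RMA in the affy package, with no version in the sources used here. The deposited intensity is on a linear scale, so log2 was taken before any fit. The intensities were normalised between arrays, so a slope after cordycepin is relative to the other transcripts on the same arrays, and the fall of total mRNA is not in the values. The arrays' medians ran from 50.3 to 68.6, and the number of arrays limits the precision.

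Of 22810 probe sets, the platform table gives exactly 1 gene for 13513 (59.2%) and several genes for 503, and 8794 are not named there. Of those with 1 gene, 13436 matched the TAIR10.1 annotation by Entrez identifier and 77 did not. A probe set entered the tests if at least 2 of the 20 arrays had a value at or above the table median, 61.39. The brightest probe set stood for each gene, which left 6961 of 13355 genes. Symbols are those of the platform table, which gives the locus identifier for many genes.

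Levels before cordycepin were compared with limma (3.58.1, R 4.3.3; lmFit and eBayes with a variance trend). The 4 cold arrays were set against the lone 22 °C array, which is assumed to vary like them, with 3 residual degrees of freedom. The error of this test is the spread among the 4 cold durations, so change with cold duration counts as error. Differences at each cold duration are 1 array against 1 and carry no test. Slopes came from a limma fit to all 20 arrays of 1 intercept and 1 slope on hours of cordycepin per series, with 10 residual degrees of freedom. Its error is the scatter of single arrays about their lines, not the spread between cultures. Contrasts of this fit gave each series' slope, the mean cold slope minus the 22 °C slope, each cold slope minus the 22 °C slope, and the linear trend of the cold slopes per 24 h of cold. An F test asked for any difference among the 4 cold slopes. All tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Half-lives were computed only after the 95th percentile slope of a series was set to zero decay. The tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and the plots drawn with matplotlib 3.10.9.

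Gene lists were tested with camera in limma against all other genes tested. The preset correlation of 0.01 was used, then a correlation estimated from the data, with adjustment over the 22 lists that had at least 3 measured genes. Before the data were examined, 18 lists, the tests, the alternatives and the rule for named genes were fixed. A further 17 lists were added once the platform table was seen to name few members of the fixed ones, before any value was tested. For 3 lists no member was named: cold shock domain and glycine-rich RNA-binding proteins, ABA genes, and SAUR genes. Phenylpropanoid genes and markers of differentiated cell types had no member past the filter. Named genes are, per comparison, the 5 with the largest change each way among those past the threshold whose difference from 22 °C has the same sign in all 4 cold series (for the trend, whose 24 and 36 h slopes lie on the same side of the 6 h slope), the 5 steepest slopes each way at 22 °C, 1 or 2 members per list, and COR15A. CBF1, CBF2, CBF3 and RD29A were to be named in every comparison but are not among the genes tested. Genes named outside this rule are said to be so.

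The relation of level and slope differences was given as correlations across genes, beside 100 simulations with no effect in which the arrays share errors as in the real fit. Alternatives were no filter, a filter at the 60th percentile of means, eBayes without trend, centring on reference genes, the mean of a gene's probe sets, intercepts of the lines, a 2-fold minimum, anchored slopes (the 95th percentile slope of each series set to zero), no 0 h arrays, scaled slopes (hours rescaled so that every series has equal slope spread), the change over the matched 4 h, 36 h against 6 h only, and each array left out in turn. All probe sets in place of genes was added after seeing the data, as was the mean cold slope. On simulated data with 100 changed genes of each size among 6961, the level fit recovered 67% of differences of 1 log2 unit and 94% of 2, with 11 false calls. The simulated noise was the scatter about the lines, and the simulated level difference was the same at all 4 cold durations. Real levels also change with cold duration, which counts as error in the level test. These level shares therefore do not carry over to genes whose level changes with cold duration. The contrast of cold and 22 °C slopes recovered 7% at 0.1 log2 per h and 79% at 0.3, with 4 false calls. The 6 h series slope recovered 82% at 0.1 and 100% at 0.3, with 17 false calls, and the trend 25% at 0.05 and 98% at 0.2, with 6 false calls.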

Results

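T87 is an Arabidopsis suspension culture of the Columbia accession, and cordycepin is an adenosine analogue that ends growing RNA chains. Transcripts were measured on 20 arrays, 1 for each time of cordycepin in cells at 22 °C and in cells after 6, 12, 24 and 36 h at 4 °C. The study asks how transcript amounts and stability change over time in the cold. Array medians after cordycepin at 22 °C went from 64.4 at 0 h to 50.3 at 4 h, and those of the cold arrays lay between 60.02 and 68.6. No condition has replicates. Positions are those of TAIR10.1.

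Of 8 measured small heat shock protein genes, 3 rose in the cold before cordycepin was added, and the list did not pass with an estimated correlation (adjusted p = 0.459). AT1G53540, a class I small heat shock protein gene on chromosome 1 (19980299 to 19981199), was 51.3-fold higher over the 4 cold arrays than on the 22 °C array, a log2 difference of 5.68 ± 0.53 (SE; limma adjusted p = 0.044). ATHSP22.0, a small heat shock protein gene on chromosome 4 (6370338 to 6371372), was 33.4-fold higher (5.06 ± 0.42; adjusted p = 0.037). AT2G29500, also of class I, on chromosome 2 (12633065 to 12634120), was 30.9-fold higher (4.95 ± 0.42; adjusted p = 0.037). AT1G63530 rose 13.9-fold and AT4G18280 12.5-fold. HSA32, a gene of acquired heat tolerance, rose 5.56-fold and AT5G54940, of the SUI1 family of translation initiation factors, 4.56-fold. These last genes fall outside the naming rule and were chosen after their values were seen. Each of the 7 was higher on all 4 cold arrays. The median of the 8 small heat shock protein genes was log2 5.83 on this 22 °C array and 6.38 to 6.86 on the 22 °C arrays with cordycepin.

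Of 6961 genes, limma called these 7 higher and 0 lower in the cold, where an unadjusted p under 0.05 gave 330 higher and 287 lower. The call count was 0 with eBayes without trend and 0 without the 12 h or the 36 h array, 14 without the 24 h array and 77 higher and 9 lower without the 6 h array. Intercepts of the lines, which use all 20 arrays, gave 1755 higher and 2596 lower.

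The cold-regulated effectors did not pass the test over all genes, in which change with cold duration counts as error. A level that builds over time in the cold is hard to call there, and not passing does not show a lack of change. COR47, a dehydrin, had a log2 difference of 7.39 ± 1.07 (adjusted p = 0.127), and its difference at 6, 12, 24 and 36 h was 5.44, 7.85, 8.33 and 7.94. COR15A, which encodes a cryoprotective protein of the chloroplast, had 4.80 ± 2.13 (adjusted p = 0.572), and its difference went from 0.87 at 6 h through 5.49 at 12 h to 6.32 at 36 h. Of the 4 measured members of the CBF regulon list, 0 were called over all genes and 2 were higher when adjusted over the list alone, with a median of 6.53. The list stood above other genes by camera (adjusted p = 2.74e-05; adjusted p = 0.544 with an estimated correlation).

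**Figure D1:**
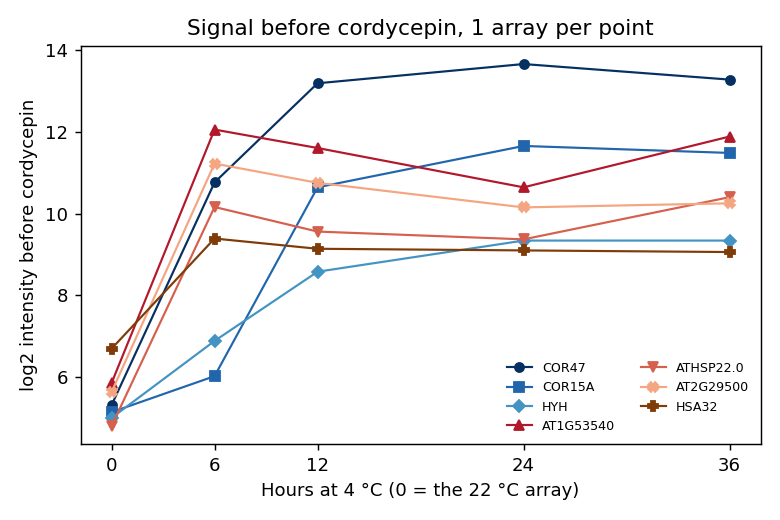
Signal before cordycepin on the log2 intensity scale (y) against hours at 4 °C (x, 0 being the 22 °C array), with 1 array per point and 1 line per gene. COR15A stood at 6.03 after 6 h and 10.64 after 12 h, while AT1G53540, ATHSP22.0, AT2G29500 and HSA32 were at or near their cold levels by 6 h.

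Of the 8 measured small heat shock protein genes in the added list, 3 rose, 5 did not pass and 5 were higher when adjusted over the list alone, with a median of 3.69 (camera adjusted p = 5.95e-10; adjusted p = 0.459 with an estimated correlation). The fixed list of heat shock proteins and factors had 3 measured genes, of which 2 rose over all genes and 2 adjusted over the list alone (camera adjusted p = 5.86e-06; adjusted p = 0.459 with an estimated correlation). The 2 that rose, ATHSP22.0 and AT2G29500, are also among the 3 of the added list, so these lists are not separate evidence. A mixed list of cold-responsive, LEA and dehydrin genes had a median of 2.00 with 0 of 7 called (8.25e-04; adjusted p = 0.544 with an estimated correlation), SRC2 having 2.41 ± 0.42. Expansins and xyloglucan endotransglucosylases, enzymes that loosen or remodel cell walls, had a median of 1.87 with 0 of 11 called (adjusted p = 9.35e-03; adjusted p = 0.459 with an estimated correlation). XTH18 of this list had 4.31 ± 0.50 (adjusted p = 0.0789).

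Organelle-encoded transcripts had a median of 0.16, with 0 of 74 called and 3 higher when adjusted over the list alone (camera up, adjusted p = 2.24e-06; adjusted p = 0.702 with an estimated correlation). Within them, rbcL, the large subunit of Rubisco, had 1.72 ± 0.25 (adjusted p = 0.127) and cox1, a subunit of cytochrome oxidase, was 2.82-fold higher without passing (adjusted p = 0.135). Plastid-encoded genes (0 of 62 called) had a median of 0.13 (4.69e-05; adjusted p = 0.702 with an estimated correlation) and mitochondrion-encoded genes (0 of 12) 0.36 (1.29e-04; adjusted p = 0.650 with an estimated correlation). The extended ribosomal protein list stood below other genes, with a median of −0.24 and 0 of 74 called (7.67e-06; adjusted p = 0.702 with an estimated correlation), AT5G67510 having −1.10 ± 0.36. Ribosome biogenesis factors had a median of −0.35, with 0 of 21 called (9.87e-04; adjusted p = 0.702 with an estimated correlation) and PCN at −0.57. Centring on reference genes moved the median of all genes from −0.078 to 0.031.

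The other 12 lists of at least 3 genes did not pass. Decay factors, with AT3G58560 at −0.58, had a median of −0.11, 0 of 13 called and 0 adjusted over the list alone, and the sign of that median turned with reference-gene centring (0.00252). The fixed ribosomal protein list (AT5G02870 −0.30), the nuclear photosynthesis list (LHCB4.1 −0.34) and the reference genes (AT4G26410 −0.22) had 0 called, and 0 adjusted over the list alone. The reference genes' median of −0.06 also turned sign with that centring (0.0502), as did that of the nuclear respiratory subunits, from −0.06 to 0.0444. Among smaller fixed lists, STZ, a zinc finger repressor, had 2.98 ± 0.39 (adjusted p = 0.0987), and was higher when adjusted over the list alone, which holds 1 gene. None of GI (1.08 ± 0.77), ATSPS4F (2.12 ± 1.22), GSTU25 (1.74 ± 1.15), PRL (−0.83 ± 0.49), WRKY53 (0.69 ± 0.66) or IAA18 (0.37 ± 0.44) passed in its list or over all genes. In the added lists, PUB19 had 2.82 ± 0.48, bZIP44 1.71 ± 0.35, UGT85A2 −1.19 ± 0.25, SWEET1 1.23 ± 0.35, TUB7 −0.65 ± 0.22, NRPC2 −0.67 ± 0.27, AT5G02570 0.57 ± 0.22 and MPPBETA −0.27 ± 0.20, and 0 of these passed over all genes.

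Taken 1 array against 1 and without a test, 245 genes were at least 2-fold higher after 6 h of cold, 585 after 12 h, 642 after 24 h and 484 after 36 h. The counts at least 2-fold lower were 54, 196, 398 and 209. At all 4 durations 134 genes were at least 2-fold higher and 19 at least 2-fold lower.

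After cordycepin at 22 °C, the transcripts of all 8 measured core histone genes, each an H2B gene, fell relative to other transcripts. HTB2 had a slope of −0.91 log2 per h and HTB11 −0.81, and the list's median was −0.71 (camera adjusted p = 1.75e-03; adjusted p = 0.620 with an estimated correlation). AT5G16250, on chromosome 5 (5310052 to 5310951), had the most negative slope past the threshold, −1.24 ± 0.09 (limma adjusted p = 1.58e-07), and AT3G42725, AT2G42110, AT3G02640 and the H2B gene AT3G53650 lay between −1.10 and −1.06. The decay factor list also fell, with 10 of 13 members lower over all genes and 10 adjusted over the list alone (2.87e-02; adjusted p = 0.620 with an estimated correlation). Ribosome biogenesis factors had 14 falling and 1 rising of 21 (3.35e-02; adjusted p = 0.738 with an estimated correlation).

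Transcripts that rose at 22 °C relative to the others included those of 36 of 42 nuclear-encoded respiratory chain subunits (1.66e-10; adjusted p = 0.620 with an estimated correlation). Organelle-encoded genes had 46 of 74 rising and 1 falling, the same counts adjusted over the list alone (3.43e-08; adjusted p = 0.620 with an estimated correlation), and plastid-encoded genes 42 of 62 rising and 1 falling (1.26e-08; adjusted p = 0.620 with an estimated correlation). The most positive slopes past the threshold were those of the pseudogene AT2G03540, 1.00 ± 0.29, and of AT3G03550, 0.88 ± 0.06, with AT2G03390 at 0.80, AT3G28580 at 0.78 and AT1G20120 at 0.77. These directions hang on the zero point. With anchored slopes the medians of the respiratory subunits (0.125), the organelle-encoded genes (0.164) and the plastid-encoded genes (0.174) became −0.151, −0.112 and −0.103, and 38 of 42 respiratory subunits fell.

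In the cold, the genes with the steepest slopes at 22 °C had slopes much nearer 0. AT5G16250 had −0.05, −0.11, −0.10 and −0.11 log2 per h in the 6, 12, 24 and 36 h series, and HTB2 went from log2 12.12 to 8.54 over 4 h at 22 °C and from 12.04 to 11.27 over 12 h in the 6 h series. Over all genes, 2681 fell and 1641 rose at 22 °C. In the 6 h cold series 251 fell and 317 rose, in the 12 h series 504 and 787, in the 24 h series 76 and 9, and in the 36 h series 17 and 1. The 5 series share 1 error per gene, scatter about the 22 °C line included, so these counts do not measure how far decay slowed. Over the mean of the 4 cold slopes, a test added after seeing the data, 1129 fell and 1502 rose. The interquartile range of slopes was 0.308 at 22 °C and 0.0412, 0.0477, 0.0362 and 0.0353 in the 6, 12, 24 and 36 h series, so that at 22 °C the slopes spread 7.67 times as widely as the cold mean. Over the matched 4 h the change spread 4.96 times as widely, and without the 22 °C 4 h array the slopes spread 12.5 times as widely. With the 95th percentile slope set to zero decay, the median half-life was 3.05 h at 22 °C and 16.4, 20.4, 33.6 and 28.4 h in the cold series. These values follow the spread of slopes in a series, noise included, and assume that transcription had stopped. They are not measured half-lives. Across genes, which are not independent replicates, the rank correlation of cold and 22 °C slopes was 0.391, 0.22, 0.385 and 0.373.

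The split of falling and rising genes depends on the zero point: with reference-gene centring it became 97 and 210 in the 6 h series and 714 and 64 in the 12 h series, and with anchored slopes 5952 fell and 73 rose at 22 °C. Without its 0 h array the 6 h series gave 0 and 2 and the 12 h series 0 and 0.

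**Figure D2:**
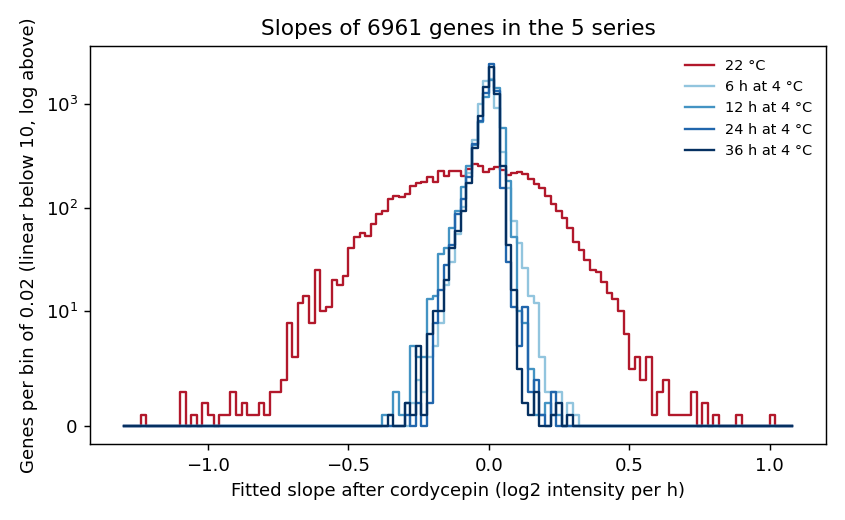
Numbers of genes per bin of 0.02 log2 per h (y, linear below 10 and logarithmic above) against the fitted slope after cordycepin (x, log2 intensity per h), with 1 line for each of the 5 series. Slopes at 22 °C reached from −1.24 to 1.00, and the interquartile range of slopes in the cold series was at most 0.0477.

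Against 22 °C, the histone transcripts that fell fast had far less negative slopes in the cold. HTB2 differed by 0.83 ± 0.06 log2 per h (limma adjusted p = 3.11e-07) and HTB11 by 0.74 ± 0.07, and all 8 H2B genes passed, with a median difference of 0.65 (camera adjusted p = 2.64e-03; adjusted p = 0.696 with an estimated correlation). AT5G16250 differed by 1.15 ± 0.09, and AT3G42725, AT3G02640, AT2G42110 and the H2B gene AT3G53650 by 1.03, 1.01, 1.01 and 0.98. AUR1, the Aurora kinase gene of cell division, differed by 0.65 ± 0.03 (adjusted p = 1.71e-08), its slope being −0.66 at 22 °C and −0.01 over the cold series. UBC20 and UBC19, ubiquitin-conjugating enzymes, differed by 0.62 and 0.39.

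Transcripts of the decay machinery followed the same direction, with 10 of 13 members less negative in the cold over all genes and 10 adjusted over the list alone (median 0.25; camera adjusted p = 1.39e-02; adjusted p = 0.696 with an estimated correlation). LSM1A, a subunit of the decapping activator, differed by 0.36 ± 0.03 and AT2G45810, a DEAD-box helicase gene, by 0.32 ± 0.04. Ribosome biogenesis factors had 15 less negative and 1 more negative of 21 (1.39e-02; adjusted p = 0.717 with an estimated correlation), with YAO at 0.36 ± 0.04 and AT1G50920 at 0.28 ± 0.03. With scaled slopes, which remove the difference in spread between series, 8 of 13 decay factors and 14 of 21 biogenesis factors were past the threshold in that direction and 1 of 8 H2B genes was.

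Nuclear-encoded respiratory subunits went the other way, with 34 of 42 more negative in the cold and 0 less negative (median −0.11; camera adjusted p = 6.29e-10; adjusted p = 0.696 with an estimated correlation). AT2G20360 and AT2G33220, subunits of complex I, differed by −0.23 ± 0.04 each. Of the organelle-encoded genes 39 of 74 were more negative and 2 less negative over all genes, and 38 and 2 adjusted over the list alone (2.00e-07; adjusted p = 0.696 with an estimated correlation). The plastid-encoded genes had 35 of 62 more negative and 2 less negative (1.33e-07; adjusted p = 0.696 with an estimated correlation), with accD at −0.37 ± 0.07 and ndhE at −0.50 ± 0.10. Mitochondrion-encoded genes had 4 of 12 more negative, orfX at −0.30 and ccb382 at −0.15 among them, and did not pass as a list (camera adjusted p = 0.245). The median difference of this list, 0.0289, and its camera direction, down, differ in sign. With anchored slopes 6 of these 12 were less negative and 0 more negative. The directions of the respiratory, organelle and plastid lists turned with anchored slopes, with 31 of 42, 30 of 74 and 24 of 62 then less negative in the cold, and with scaled slopes 0, 3 and 2 were called more negative.

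Single genes outside these lists with a more negative slope in the cold were AT3G03550 (−0.88 ± 0.07), AT2G03540 (−0.79 ± 0.29), AT3G28580 (−0.78 ± 0.10), AT1G22030 (−0.73 ± 0.06) and AT1G25400 (−0.73 ± 0.08). AT2G03540 had 0.0165 without the 0 h arrays, 0.70 with scaled slopes and up to 0.00204 with 1 array left out, and none of these passed. Of the small heat shock protein genes, AT2G29500 was more negative (−0.49 ± 0.10) and AT1G54050, of class III, less negative (0.70 ± 0.13), and the list had 1 less and 2 more negative of 8, the list not passing. The fixed heat shock list had 1 of 3 more negative over all genes, again AT2G29500, and 1 adjusted over the list alone, ATHSP22.0 having −0.15 ± 0.09 without passing.

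COR47 (−0.09 ± 0.04; adjusted p = 0.0587), COR15A (−0.12 ± 0.08), and the list of the CBF regulon (0 of 4 called, 0 adjusted over the list alone) did not pass, and with anchored slopes COR47 had 0.14 and passed. STZ (0.26 ± 0.14) and WRKY53 (0.04 ± 0.17) did not pass, and with scaled slopes STZ had −1.12 and WRKY53 −1.24, both past the threshold. At 22 °C STZ went from log2 8.09 to 6.01 within 0.5 h and to 5.53 at 4 h, which a straight line does not follow. Of the transcription factors in the added list 9 of 17 were less negative, with bZIP19 at 0.51 and WRKY20 at 0.41, and 1 more negative (adjusted p = 0.129). Ubiquitin enzymes had 15 less and 4 more negative of 28 (adjusted p = 0.122), and RNA polymerase, Mediator, THO and LSM subunits 11 and 7 of 24, NRPA2 of RNA polymerase I among them at 0.49 ± 0.05 (adjusted p = 0.837). Of these 24, 21 were less and 0 more negative with anchored slopes, and 9 and 0 with scaled slopes. The extended ribosomal protein list had 13 less and 3 more negative of 74 (adjusted p = 0.805), AT5G67510 at 0.38 and AT1G15250 at 0.31, and its median of 0.0022 and its camera direction, down, differ in sign. Its counts hang on the zero point, with 74 less and 0 more negative with anchored slopes and 5 and 1 with reference-gene centring.

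The remaining lists held called genes both ways or few. Expansins and endotransglucosylases had 4 less and 2 more negative of 11, with EXPA4 at 0.57 and EXLA1 at 0.45 (adjusted p = 0.878). Glycosyltransferases had 4 less and 3 more negative of 16, with UGT88A1 at 0.30 and UGT71B5 at −0.35 (adjusted p = 0.380), and glutathione transferases 1 and 1 of 4, with GSTU27 at 0.17 and GSTL3 at −0.23 (adjusted p = 0.380). The mixed list of cold-responsive, LEA and dehydrin genes had 1 less and 2 more negative of 7, with COR27 at 0.37 and AT4G30660 at −0.21 (adjusted p = 0.573), and the CCT and tubulin list 1 and 3 of 15, with TUB7 at 0.17 and TUB1 at −0.21 (adjusted p = 0.172). With anchored slopes 0 members of the mixed cold-responsive, CCT and tubulin, glutathione transferase, reference or photosynthesis lists were more negative, and AT4G30660, TUB1, RCA and SWEET1 had values above 0. Photosynthesis genes had 2 less and 1 more negative of 6, and 4 and 1 adjusted over the list alone, with ATPC1 at 0.06 and RCA at −0.08. With reference-gene centring or scaled slopes 0 of the 6 were called over all genes, and the ATPC1 call was not kept in 8 of 29 alternatives. Reference genes had 2 less and 1 more negative of 5, the same adjusted over the list alone, with AT2G28390 at 0.26 and PEX4 at 0.15. The fixed ribosomal protein list had 1 of 3 less negative, also adjusted over the list alone, AT5G02870 at 0.06 and AT3G09630 not passing at 0.04. Over all genes 0 of these 3 were called with reference-gene centring or scaled slopes and 3 with anchored slopes. The AT5G02870 call was lost in 5 of 29 alternatives. GI was less negative (0.15 ± 0.03), as was AUR1 of the cell cycle pair, of which PRL was more negative (−0.27 ± 0.05), and each of these calls held adjusted over the list alone. SWEET1 was more negative (−0.18 ± 0.07), a call not kept in 16 of 28 alternatives, as that of RCA was not in 17 of 29, and SWEET2 (0.07 ± 0.09) did not pass, and neither IAA18 (−0.07), ATSPS4F (−0.13) nor GSTU25 (−0.03) passed in its list or over all genes. With anchored slopes IAA18 had 0.1601 and GSTU25 0.2017, both past the threshold.

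Over all genes, 2577 had a less negative and 1495 a more negative slope in the cold, of which 2504 fell and 1455 rose at 22 °C. Without the filter the balance turned, with 2726 less and 3344 more negative, and 2868 falling and 3690 rising at 22 °C. Over 4 h of cordycepin at 22 °C the arrays' lower quartile went from 14.9 to 18.8 while the median went from 64.4 to 50.3. Dim probe sets thus gained signal there relative to brighter ones, and the part of this in the turn was not tested. By duration, the counts of less and of more negative genes were 2492 and 1471 at 6 h, 2555 and 1453 at 12 h, 2501 and 1425 at 24 h, and 2503 and 1422 at 36 h. With anchored slopes the counts were 5544 and 99, and with scaled slopes 1650 and 577. Temperature, light and time in culture differ together between these series. Whether cordycepin stopped transcription as fully at 4 °C as at 22 °C was not measured.

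**Figure D3:**
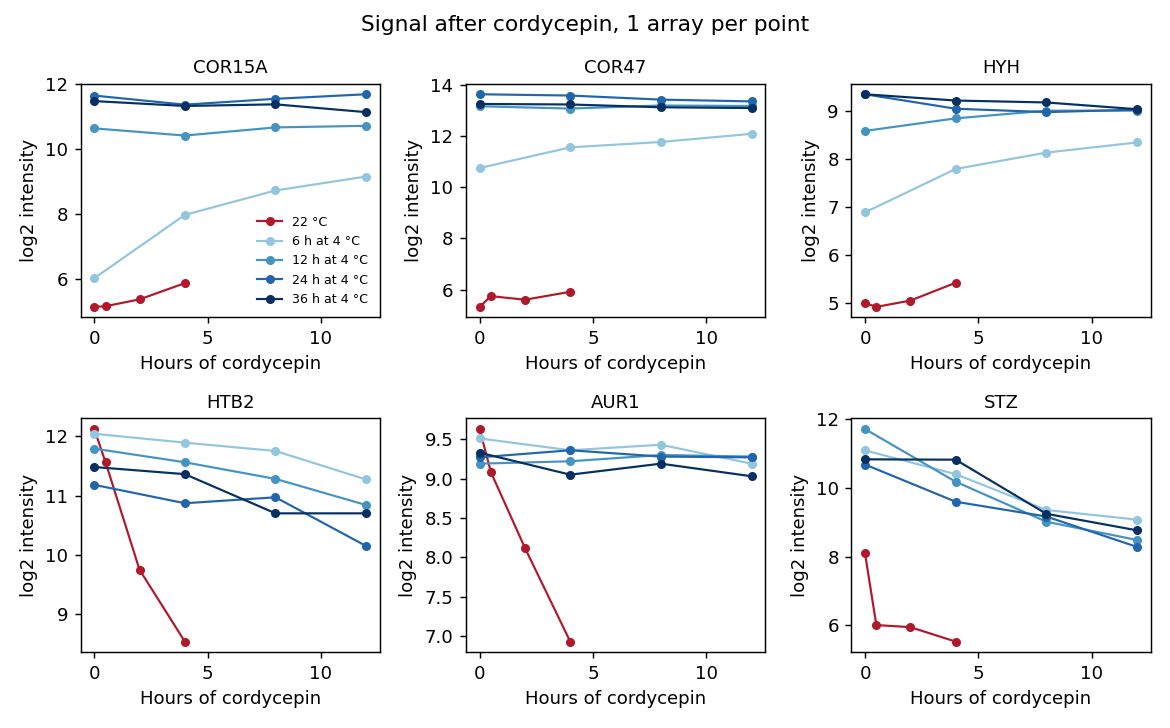
Log2 intensity (y) against hours of cordycepin (x) for COR15A, COR47, HYH, HTB2, AUR1 and STZ in the 5 series, with 1 array per point and lines joining the arrays of a series. HTB2 and AUR1 dropped over 4 h at 22 °C, from 12.12 to 8.54 and from 9.63 to 6.93, and COR15A went from 6.03 to 9.16 over the 12 h of cordycepin in the series begun after 6 h of cold.

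Among the cold series, 10 of the 11 genes with a called falling trend rose after cordycepin in the series begun after 6 h of cold. With anchored slopes 7 of the 11 had a slope above 0 there by over 2 standard errors, and with reference-gene centring 10. None of the 11 was called in the test of levels, which counts change with cold duration as error. COR15A went from log2 6.03 through 7.98 and 8.73 to 9.16 there, a slope of 0.25 log2 per h, and had −0.02 in the 36 h series, a trend of −0.175 ± 0.0274 per 24 h of cold (limma adjusted p = 0.0197). COR47 went from 10.76 to 12.10, with a trend of −0.0818 ± 0.0137 (adjusted p = 0.0302), and HYH, a bZIP factor related to HY5, from 6.89 to 8.34, with a trend of −0.107 ± 0.016. AT1G68500 had the most negative trend past the threshold, −0.191 ± 0.0233 (limma adjusted p = 5.45e-03). Its slope went from 0.03 in the 6 h series, not past the threshold, to −0.24 in the 36 h series. In the 6 h series its signal was only log2 4.1 to 4.54, below the table median of 5.94, which leaves little room for a fall there. AT3G49210 and AT1G51090 also began that series low, at 4.39 and 4.02, and went to 5.77 and 5.55. AT3G56290 (−0.140), AT3G49210 (−0.131) and AT5G64850 (−0.126) passed as well. With the alternatives and each array left out, the call was lost in 17 of 28 for AT3G56290, 16 of 28 for COR47, 14 of 27 for AT3G49210, 10 of 28 for UGT87A2, 7 of 28 for COR15A, 6 of 28 for AT5G64850 and 3 of 27 for AT1G68500. AT1G16850, AT1G51090, AT5G50100 and HYH pass too but lie outside the naming rule and were chosen after their values were seen.

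Of the CBF regulon list 2 of 4 members fell over all genes and 3 adjusted over the list alone, with a median of −0.139 (camera adjusted p = 9.10e-09; adjusted p = 0.0343 with an estimated correlation). With anchored slopes 0 of the 4 were called over all genes, with a median of −0.12. The mixed list of cold-responsive, LEA and dehydrin genes, most of whose measured members are neither, had 0 of 7 called, 2 adjusted over the list alone and a median of −0.05 (adjusted p = 1.51e-04; adjusted p = 0.031 with an estimated correlation), COR27 having −0.09. Glycosyltransferases had 1 of 16 falling, UGT87A2 with −0.101 ± 0.0165, and 3 adjusted over the list alone (1.29e-04; adjusted p = 0.031 with an estimated correlation), UGT84A1 having −0.106 without passing. Their median of −0.0319 became −0.0131 with anchored slopes, with 0 of 16 called over all genes. Mitochondrion-encoded genes had 0 of 12 called, with nad4 at −0.04 (camera down, 4.74e-03; adjusted p = 0.695 with an estimated correlation). The extended ribosomal protein list had 0 of 74 called and a median of 0.006 (camera up, 2.41e-03; adjusted p = 0.843 with an estimated correlation), which turned to −0.00622 with reference-gene centring. Ribosome biogenesis factors had 0 of 21 called and a median of 0.014 (camera up, 2.21e-03; adjusted p = 0.843 with an estimated correlation), which became 0.00179 with reference-gene centring.

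The other lists had 0 called over all genes. Adjusted over the list alone, GI (−0.04) and GSTU25 (−0.10) fell, each alone in its fixed list, and GSTU25 also in the glutathione transferases, and 0 genes passed in the other lists. Values without a call included those of AT5G37670 (0.105 ± 0.0663) in both heat shock lists, ATSPS4F (−0.12 ± 0.06), WRKY53 (−0.09 ± 0.06), XTH19 (−0.08 ± 0.03) and AT2G28720 (−0.07 ± 0.03), and STZ had 0.02 ± 0.05.

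In all, limma called 11 genes with a falling trend and 0 with a rising trend, where an unadjusted p under 0.05 gave 265 and 197. The F test found 193 genes with any difference among the 4 cold slopes. The 11 calls became 0 without the 0 h arrays, 0 without the 0 h array of the 6 h series or the 12 h array of the 36 h series, 29 without the 4 h array of the 6 h series, and 1 falling and 1 rising with anchored slopes, where the median trend of the 11 was −0.0955, against −0.114 as reported. With reference-gene centring 13 genes fell and 0 rose, 10 of the 11 among them. With the 36 h and 6 h slopes alone, 17 genes fell and 0 rose, where an unadjusted p under 0.05 gave 340 and 453.

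Genes with a higher level in the cold tended to have a more negative slope difference. Arrays shared by both measures can give such a relation without any effect, but do not account for all of it here. Of the 7 genes called higher, AT1G53540, AT2G29500, AT1G63530 and AT4G18280 had a more negative slope in the cold, where 1.5 are expected from independence. AT5G54940 had a less negative slope, where 2.6 are expected, and ATHSP22.0 and HSA32 were not called. Before cordycepin at 22 °C the first 4 had signals of 58.1, 50, 26.5 and 151, where the table median was 61.39. Their slopes at 22 °C were 0.349, 0.469, 0.478 and 0.325. Across all 6961 genes, which are not independent replicates, Pearson's r of the level and slope differences was −0.203 and Spearman's rho −0.143. The 100 simulations with no effect gave −0.509 and −0.474 on average. Simulated genes vary by noise alone, so these correlations are not on the same scale as the observed ones. The covariance was −0.0291, against −0.00734 in the simulations. Slopes that leave out the 0 h arrays share no array with the level difference, and with them the correlations were −0.272 and −0.234. No p is given for these 2 correlations.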

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

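The tests of the change over 0 to 2 h at 22 °C and of the trend under the scaling alternatives were chosen only after the result was seen. No condition had the replicates among which an outlying array is sought, and single arrays were left out in turn instead.

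Slopes in the cold series differed with cold duration, by the test of the trend itself, for 11 genes. Per 24 h of cold the trend was −0.191 for AT1G68500, −0.175 for COR15A, −0.14 for AT3G56290, −0.131 for AT3G49210, −0.126 for AT5G64850 and −0.114 for both AT1G16850 and AT1G51090. It was −0.107 for HYH, −0.101 for UGT87A2, −0.0885 for AT5G50100 and −0.0818 for COR47. The F test of any difference among the 4 cold slopes picked out 193 genes.

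All 11 genes had slopes above 0 in the series begun after 6 h of cold, with a median of 0.107 log2 per h. A low 0 h array there cannot be told apart: without it all 11 slopes were above 0, with a median of 0.0692 against a median standard error of 0.0221, but these genes were chosen for their slopes on the same arrays, and without it the trend calls went from 11 to 0 and the series gave 0 falling and 2 rising genes. For the rise in the 6 h series, normalisation lifting stable transcripts cannot be told apart, since the 348 other genes with the highest slopes in the later cold series had a median of 0.0207 and a 95th percentile of 0.117 in the 6 h series, and the lowest of the 11, AT1G68500, stood at 0.0328 ± 0.0224. In that series 7 of the 11 slopes lay above 0 by over 2 standard errors with anchored slopes, and 10 with reference-gene centring. For the trend, such a lift as the whole cause is argued against only as far as these 2 corrections measure it. The median trend of −0.114 was −0.0955 with anchored slopes (median SE 0.0183) and −0.127 with reference-gene centring (0.0218). All 11 stayed below 0 by over 2 standard errors under both. Each correction shifts every gene's trend alike and these genes were chosen for trends far from 0, so that count adds little. The smaller trends with anchored slopes left 1 of the 11 called, against 10 with centring. A candidate explanation is that these transcripts were still accumulating under cordycepin at 4 °C. For this, 565 other genes at least 2-fold higher after 24 h than after 6 h of cold were examined. Over the 4, 8 and 12 h arrays of the 6 h series their median slope was 0.00503, a small shift. It lay above the 99th percentile of 10000 random lists matched on level (0.00189). Those lists drew genes singly and so leave out that genes induced together can move together on the same arrays. The percentile therefore does not decide for accumulation. The trend calls fell to 0 without the 0 h arrays.

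By the test of the difference between cold and 22 °C slopes, 2577 genes had a less negative and 1495 a more negative slope in the cold. Noise over the shorter span at 22 °C is argued against, since the interquartile range of the change over the first 4 h was 4.96 times the cold mean, 1.32 against 0.205 to 0.351 log2 units. A 22 °C 4 h array standing apart is argued against, since the change over 0 to 2 h there, which leaves it out, had an interquartile range of 1.09, 4.1 times the cold mean over 4 h. Dimmer light or culture time in place of temperature cannot be told apart, since 1 series, at 22 °C, stood in the brighter light and all cold series in the dimmer. Transcripts still accumulating under cordycepin at 4 °C, the candidate given above for the trend genes, would also flatten cold slopes. That was not tested for these genes, so a less negative slope does not by itself show greater stability. With each series in turn set against the other 4, 1 of the 5 splits, the real one, gave as many as its 4072 genes and the highest other gave 2552, and 5 splits are too few for a share under 0.05. Series other than the 22 °C one thus also called many genes when set apart, each against a group that held the 22 °C series.

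Small heat shock protein transcripts were higher in the cold before cordycepin, 3 of 8 past the threshold. A lone 22 °C array standing low as the whole cause is argued against, since the lowest median of the list on the 4 cold arrays lay 2.74 log2 units above the highest of the 4 arrays at 22 °C, 6.86. The 0 h array was the lowest of these, 5.83 against 6.86, 6.66 and 6.38, so the fold differences rest on the lowest 22 °C reading. The later arrays had cordycepin and belong to the same series, so they cannot show whether that series stood low. Probe sets that read several members of the family cannot be told apart from a joint rise, since the lowest correlation between members at least 2-fold higher was 0.72, neither near 1 nor under the bound of 0.5 set for the test. Cold, light and culture time stay open together as untested biological causes. For the 7 genes called higher, 1 of the 5 choices of the lone array, the real one, gave as many and the highest other gave 0, and 5 choices are too few for a share under 0.05.

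Among 5841 probe sets past the filter for which the platform table does not give exactly 1 gene, and which no comparison of genes used, 125 were at least 2-fold higher and 16 at least 2-fold lower at all 4 cold durations than on the 22 °C array.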

How the results depend on the processing

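The tests over all probe sets were chosen after seeing the data. Arrays without replicates, signals relative to other transcripts and a single 22 °C series limit all of these results. The direction of the difference in slope spread and of the correlation between level and slope differences held under all alternatives run. For single named genes, 268 of 314 level values, 265 of 267 slopes at 22 °C, 1626 of 1729 slope differences and 838 of 915 trends kept direction and side of the threshold, many of them values that passed neither as reported nor in the alternative. Of the values that passed as reported, the call and direction were kept in 34 of 50 for the level (5 genes), 265 of 267 for slopes at 22 °C (10 genes), 1355 of 1443 for slope differences (50 genes) and 121 of 194 for trends (7 genes). The level fit without its 22 °C array is impossible, and series cut to 0 and 4 h were not fitted as lines, being covered by the matched 4 h change. Where a count rose with more probe sets tested or fell with fewer, the number tested changed by construction, and for the other changes the cause was not tested.

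Without a filter, 2868 genes fell and 3690 rose at 22 °C, 2726 were less and 3344 more negative in the cold, and 3 rose in the 24 h and 0 in the 36 h series. With the stricter filter, 145, 297, 25 and 1 genes fell in the 6, 12, 24 and 36 h series and 2 and 0 rose in the 24 and 36 h ones. Without the variance trend, 0 genes were higher in the cold, and 5 and 2 rose in the 24 and 36 h series. Reference-gene centring gave 97 falling and 210 rising at 6 h, 64 rising at 12 h, 3 rising at 24 h, and 46 falling and 0 rising at 36 h. All probe sets gave 4861 falling and 3058 rising at 22 °C, 443 and 636 at 6 h, 936 and 1341 at 12 h, 5 rising at 24 h, 4698 less and 2791 more negative in the cold, and 7305, 7373, 7222 and 7253 called by duration. Intercepts of the lines gave 1755 higher and 2596 lower. Anchored slopes gave 5952 falling and 73 rising at 22 °C, 5377 and 67 at 6 h, 4603 and 18 at 12 h, 2071 falling at 24 h, 2773 and 4 at 36 h, 5544 less and 99 more negative in the cold, and 1 falling and 1 rising trend. Without the 0 h arrays, 96 fell and 125 rose at 6 h, 153 and 28 at 12 h, 139 and 16 at 36 h, and 0 trends fell. Scaled slopes gave 1650 less and 577 more negative, and 629, 1943, 419 and 349 by duration. The 36 h against 6 h slopes alone gave 17 falling. With an estimated correlation, 0 of 10 lists passed for the level, 0 of 6 for the slope difference and 3 of 6 for the trend.

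Slope differences that changed sign were, with anchored slopes, COR47 0.1395, RCA 0.1501, IAA18 0.1601, GSTU25 0.2017, AT4G30660 0.01932, ccb382 0.07619, TUB1 0.02141 and SWEET1 0.04802. With scaled slopes they were AT2G03540 0.7002, STZ −1.122, ATPC1 −0.000337, RCA 0.001171, WRKY53 −1.237 and AT4G30660 0.05215. AT2G03540 had 0.01647 without the 0 h arrays.

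With 1 array left out in turn, genes higher in the cold ranged from 0 to 77 and lower from 0 to 9. Without the 0 h array of the 6 h series they were 77 and 9, without that of the 24 h series 14 and 0, and without that of the 12 h or 36 h series 0 and 0. Falling trends ranged from 0 to 29, with 0 without the 0 h array of the 6 h or the 12 h array of the 36 h series, 1 without the 0 h array of the 12 h or 36 h series, 19 without the 22 °C 0 h array and 29 without the 4 h array of the 6 h series. They numbered 5 without the 8 h array of the 6 h, 12 h or 36 h series or the 4 h array of the 36 h series, 6 without the 12 h array of the 12 h or the 0 or 4 h array of the 24 h series, and 7 without the 8 h array of the 24 h series. Rising trends ranged from 0 to 1, with 1 without the 4 h array at 22 °C or of the 6 h series. In the 6 h series falling genes ranged from 0 to 657 and rising genes from 2 to 634, with 657 and 634 without the 22 °C 0 h array, 453 falling without the 22 °C 4 h array, 0 and 2 without its 0 h, 153 and 191 without its 8 h and 12 and 58 without its 12 h array. In the 12 h series they ranged from 0 to 935 and from 0 to 1301, with 935 and 1301 without the 22 °C 0 h array, 0 and 0 without its 0 h, 515 rising without its 8 h and 8 and 2 without its 12 h array. In the 24 h series they ranged from 0 to 488 and from 0 to 157. Falling genes there were 488, 201, 127 and 213 without the 0, 0.5, 2 and 4 h arrays at 22 °C, and 0, 35, 18 and 1 without its own 0, 4, 8 and 12 h arrays. They were 138 and 44 without the 0 and 8 h arrays of the 6 h series, 43 without the 8 h array of the 12 h series, and 44 and 45 without the 8 and 12 h arrays of the 36 h series. The rising count of 9 there became 157, 29, 22 and 35 without the 22 °C arrays in order of time, 19, 15, 2 and 4 without those of the 6 h series, 5, 4, 2 and 3 without those of the 12 h series and 0, 4, 0 and 0 without its own. It became 5, 2 and 2 without the 0, 8 and 12 h arrays of the 36 h series. In the 36 h series they ranged from 0 to 358 and from 0 to 302, with 358, 56, 37 and 86 falling and 302, 6, 5 and 41 rising without the 22 °C arrays and 1, 10, 4 and 0 falling without its own. Its rising count of 1 became 2 without the 0 h array of the 6 h series and 0 without each other cold array, except the 8 and 12 h arrays of the 12 h series and the 4 and 8 h arrays of the 24 h series, without which it was 1. At 22 °C, 2268 to 2731 genes fell and 1149 to 1730 rose. In the cold 2208 to 2618 were less and 1073 to 1609 more negative, and by duration 3148 to 4190, 3396 to 4155, 3250 to 4100 and 3269 to 4141 were called. The ratio of slope spreads ranged from 6.34 to 12.5 and the correlation of level and slope differences from −0.22 to −0.107, with 12.5 and −0.107 without the 22 °C 4 h array, and AT2G03540's slope difference from −2.069 to 0.002043.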

Other observations

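The tests of the mean cold slope and of transcripts that moved within 0.5 h of cordycepin were chosen only after the values were seen, and so were the genes named in this part.

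Some transcripts kept falling in the cold. Over the mean of the 4 cold slopes, limma called 1129 genes falling and 1502 rising relative to other transcripts. AT4G10270 had −0.262 ± 0.0476 log2 per h (SE), AT5G63130 −0.255 ± 0.0348, AT3G19680 −0.214 ± 0.0258 and the zinc finger gene STZ −0.208 ± 0.0243. STZ stood higher in the cold before cordycepin by 2.98 log2 units without passing that test, and its slope at 22 °C was −0.469. That line understates its early fall, since STZ went there from log2 8.09 to 6.01 within 0.5 h and to 5.53 at 4 h. AT1G69760 had −0.209 ± 0.0222 in the cold beside 0.00403 at 22 °C. The most positive mean slopes were those of ARPN (0.259 ± 0.0367), AT5G45180 (0.224 ± 0.0367), AT2G03390 (0.221 ± 0.0315) and AT2G03540 (0.215 ± 0.0503), and the defensin gene PDF2.1 had 0.132 ± 0.0167.

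Within 0.5 h of cordycepin at 22 °C, 1 array against 1 and without a test, 423 genes were at least 2-fold lower and 68 at least 2-fold higher. Of the 423, 335 were at least 2-fold lower at 4 h. The change over 0.5 h was −5.38 log2 units for AT5G20790 and −4.12 for AT4G10270, beside mean changes over 4 h in the cold of −0.48 and −1.51. Over 4 h, 1 array against 1, 1509 genes were at least 2-fold lower and 561 higher at 22 °C, against 65 and 101 in the 6 h, 97 and 4 in the 12 h, 13 and 8 in the 24 h and 6 and 0 in the 36 h cold series.

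The 68 genes higher after 0.5 h at 22 °C included AT2G03540 (4.57 log2 units), AT5G01015 (3.58), ARPN (2.96), AT5G45180 (2.71) and AT2G03390 (2.51). Of them, 60 were at least 2-fold higher at 4 h, which argues against a 0.5 h array standing apart, although a shared 0 h array enters both changes. In the cold series, which share no array with 22 °C, 54 of them had a slope above 0 in all 4 series, where 10000 random lists matched on level gave a median of 12 and at most 24, which argues against noise in dim signals. Their median level was 5.88 log2 units, against 7.47 for all genes. Stable transcripts gain signal relative to falling ones after normalisation, and this stays open for part of the set. Of the 68, 46 lay above the 95th percentile of all slopes at 22 °C, on the arrays that chose them, and 23 did so in all 4 cold series, where 26 of all genes did. That a small set of transcripts gains signal after cordycepin at both temperatures is a hypothesis, and it may hold for these 23 of the 68 rather than for all of them. Of these genes, 5 (ARPN, AT2G03130, AT2G03390, AT2G03460 and AT2G03540) start within 247 kb of chromosome 2, among 20 tested genes there, a stretch picked out for its density, so that no test applies.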
